A study of Mus musculus with 18 samples.

How the data were processed

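Gene expression was profiled in gastrocnemius muscle taken from both legs of male C57BL/6 mice at 2, 11 and 25 months of age. Each age had 6 samples and each sample was run on its own Affymetrix whole-transcript array, which gave 18 arrays. Per the labels, the samples of an age are biological replicates, the muscle was snap frozen, and biotin-labelled single-stranded cDNA was made from total RNA depleted of ribosomal RNA.

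The deposited values are intensity on a linear scale, with 1 value per probeset and array for 15300 probesets. The authors' notes name Affymetrix Expression Console 1.2.1, RMA and the genome build mm8, and the series text names GeneSpring GX 14.9; the authors state no filter that would explain the number of probesets, and the labels give no array dates or batches. Log2 was taken before every test. No probeset could be recognised as a control, so all 15300 were tested. Of these, 13592 had 1 gene symbol, 941 had several and 767 had none; the 13592 covered 13255 distinct symbols, 319 of them with more than 1 probeset. By Entrez identifier, 13542 were matched to a current RefSeq gene table, which changed 0 symbols. That table uses another build than mm8, so no positions are given.

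The main test was limma 3.58.1 in R 4.3.3: a linear model with 1 mean per age over all 18 arrays, moderated statistics, the contrasts 11 minus 2, 25 minus 11 and 25 minus 2 months, and Benjamini-Hochberg adjustment within each contrast with a threshold of 0.05. A moderated F statistic tested the 3 ages together. Errors of log2 changes are standard errors (SE) from that model, and errors of group means are standard deviations (SD) over 6 arrays. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. For arrays, the number of arrays per age limits the precision.

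A total of 29 gene lists was fixed before the data were examined, 17 of pathways and 12 of cell-type markers. The pathway lists covered denervation and acetylcholine receptor genes, collagens and extracellular matrix, oxidative phosphorylation, fatty acid oxidation, glycolysis and glycogen, cell cycle, imprinted and growth genes, p53 targets and senescence, antigen presentation and interferon response, ubiquitin ligases and autophagy, slow and fast fibre contractile genes, the circadian clock, heat shock, immediate early genes, antioxidant genes and polyamine metabolism. The marker lists covered adipocytes, Schwann cells, endothelium, smooth muscle and pericytes, fibro-adipogenic progenitors, tenocytes, satellite cells, macrophages, T and NK cells, B and plasma cells, neutrophils and erythroid cells. Each gene entered with its brightest probeset. Lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 87 tests of 29 lists in 3 contrasts, and again with an estimated correlation; fry, which asks whether a list moves 1 way on balance and compares it with no other genes, was an alternative.

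The rule for named genes, fixed with the lists, took per contrast the 10 largest rises and the 10 largest falls among called probesets with 1 symbol, passing over predicted and clone names, and from each list up to 2 members per direction with the smallest adjusted p. Where a list had no called member, the one with the smallest p was available. Genes outside the rule are named as such where they appear.

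The alternatives were the methods' own one-way test with Tukey, a further quantile normalization, centring each array on its median, leaving out dim probesets, a trended and robust variance model, array weights, a replicate block, fits with only the 2 ages compared, 1 probeset per gene, a threshold of 0.01, a fold of at least 1.5, and leaving out each array in turn. As run here, the one-way test over the 3 ages was adjusted across probesets and Tukey's p for a pair of ages was not. The array signal range (the interquartile range of an array's log2 values) as a covariate, a fit without the 3 arrays of narrowest range, and list tests without 1 array with raised skin genes were added after the data were seen. The model was tested on simulated data with 20 simulations of 25 against 11 months, each with 200 shifted probesets. It recovered 67.6% of shifts of 1.25-fold, 95.4% of 1.5-fold and 99.5% of 2-fold, with 5.36% of calls false. Recovery depends on the number of shifted probesets, as the adjusted threshold is stricter where fewer change. The real comparison called 23 probesets, so these rates may be too high for it. Col1a1 changed 1.71-fold there and did not pass limma's test (adjusted p = 0.126). Camera called the shifted list in 20 of 20 simulations and 0.357% of unshifted lists. Genes were simulated as independent of each other, so these rates do not cover lists whose genes vary together.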

Results

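Whole gastrocnemius, a calf muscle built mainly of fast fibres, was compared between male C57BL/6 mice of 2, 11 and 25 months, with 6 arrays per age. Array medians lay between 97.6 and 101 intensity units. The array signal range was 2.19 ± 0.11 at 2 months, 2.33 ± 0.08 at 11 months and 2.26 ± 0.08 at 25 months (log2 units, SD, n = 6). It was wider at 11 than at 2 months by 0.14 (two-sided exact permutation p = 0.0260), which did not pass after correction over the 3 pairs of ages (Benjamini-Hochberg p = 0.0779); for 25 against 11 months the exact p was 0.180 and for 25 against 2 months 0.225. Across probesets, which are not independent replicates, arrays correlated with r of 0.987 to 0.996 within ages and 0.977 to 0.995 between ages. The first principal component held 33.3% of the variance and averaged -14.1 ± 8.12 at 2 months, 7.89 ± 4.77 at 11 months and 6.22 ± 5.53 at 25 months (SD, n = 6). Over the 3 ages together, 2936 of 15300 probesets changed by limma's moderated F statistic.

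The comparison of 11 with 2 months sets adult against young muscle. The largest change was in Actc1, the cardiac actin that skeletal muscle makes during development: its signal fell 9.58-fold from 13.26 ± 0.51 log2 units (SD, n = 6), a log2 change of -3.26 ± 0.21 (SE; adjusted p = 7.3e-09), and a second probeset fell by 3.26. Close similarity among actin genes leaves open how much other actins add to this signal. Transcripts of fibrillar collagen fell with it, Col1a1 by 4.74-fold (from 11.49 ± 0.52 to 9.25 ± 0.30, adjusted p = 4.33e-07) and Col1a2 by 3.36-fold. In the other direction Ostn, which encodes the secreted muscle peptide musclin, rose 4.50-fold from 7.77 ± 0.67 to 9.94 ± 0.31 (adjusted p = 3.92e-06). Amy1, an amylase with close paralogs, rose 2.84-fold, and Kcnab1, a subunit of potassium channels, 2.62-fold.

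Other large rises from 2 to 11 months were in Klhl38 (2.43-fold), Inmt (2.40-fold), Eda2r (2.35-fold), the secreted glutathione peroxidase Gpx3 (2.31-fold), Aldh1a1 (2.30-fold), Ces1d (2.26-fold) and the glucose transporter Slc2a3 (2.23-fold), with SE of 0.08 to 0.20 on the log2 scale. Other large falls were in Mybph, a myosin-binding protein (3.41-fold), Col3a1 (2.51-fold), the imprinted noncoding RNA H19 (2.30-fold), Kera, a tendon proteoglycan (2.06-fold), the matrix protein Sparc (2.03-fold), Adamts20 (1.87-fold) and Mettl21e (1.87-fold). For all 10 rises of the rule and 9 of its 10 falls every array of an age lay beyond every array of the other. The exception was Kera. Chance gives this in 0.216% of splits for a gene not picked by its change; as these genes were picked that way, the count describes them and tests nothing.

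**Figure D1:**
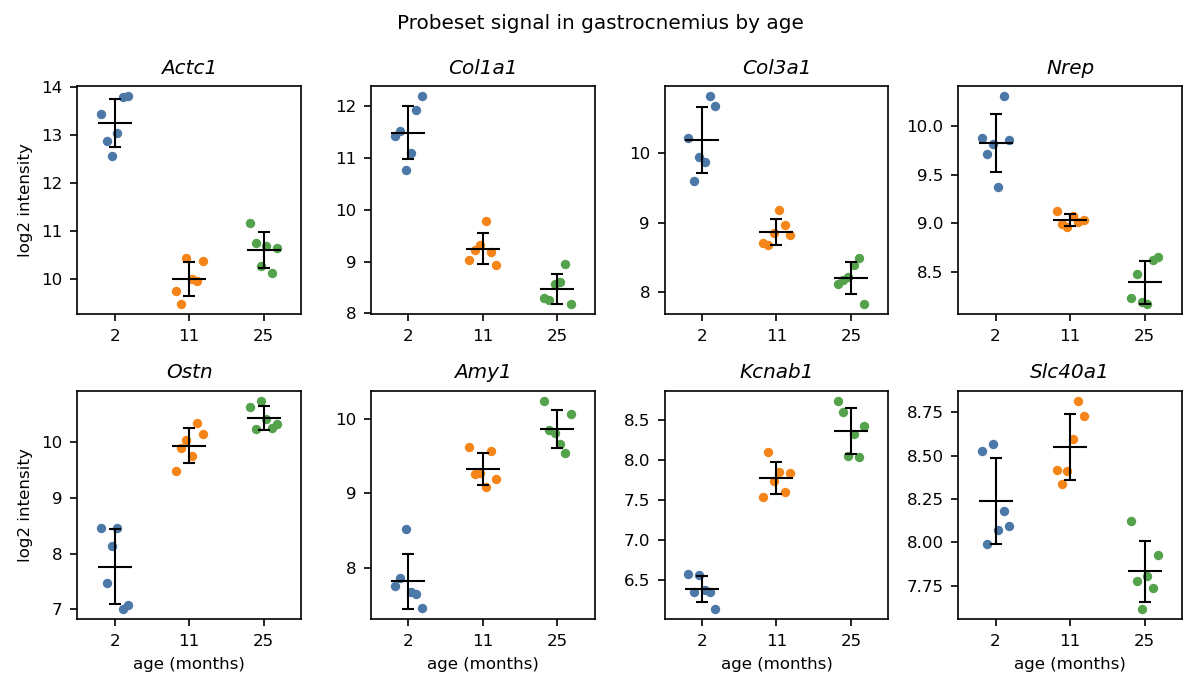
Log2 signal (vertical axes) of 8 genes by age in months (horizontal axes); points are arrays, bars are the mean with the SD, n = 6. Actc1, Col1a1, Col3a1 and Nrep are lower and Ostn, Amy1 and Kcnab1 higher at 25 than at 2 months, and Slc40a1 falls from 8.55 at 11 months to 7.83 at 25.

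Matrix genes fell as a group: 23 of 30 measured collagen and extracellular matrix genes fell and 1, Dcn, rose (24 and 1 adjusted over the list alone), with a mean log2 change of -0.51 (95% interval -0.66 to -0.37). Camera's adjusted p was 6.19e-16. Over the alternatives it ranged from 3.35e-25 to an adjusted p = 0.123 with an estimated correlation. The call of Dcn, a proteoglycan, ended with the signal range as a covariate (adjusted p = 0.119, the highest of a range from 0.00235). Tenocyte markers moved with them, with 6 of 8 lower and 0 higher, among them Kera and Col11a1 (log2 change -0.59, SE 0.07). Their camera adjusted p was 4.48e-06, with a range from 6.89e-09 to an adjusted p = 0.123 with an estimated correlation. Fibro-adipogenic progenitor markers had 2 of 12 lower, Mfap4 (1.63-fold) and Mfap5 (1.21-fold), and the list as a whole did not pass (adjusted p = 0.264).

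Genes of imprinted loci and growth had 6 of 14 lower and 2 higher (6 and 4 adjusted over the list alone). Peg3 fell 1.62-fold (SE 0.07), Plagl1 1.28-fold, and the growth factor Igf1 fell by 0.58 log2 units. Camera gave an adjusted p of 0.0329, ranging over the alternatives from 8.29e-05 by fry to an adjusted p = 0.148 with an estimated correlation. It was 0.0728 without 2 months replicate 1 and 0.0662 without 11 months replicate 1. Among ubiquitin ligase and autophagy genes 8 of 19 rose and 0 fell (9 and 1 adjusted over the list alone), led by the ligase Fbxo32 (2.11-fold, SE 0.15) and the cargo receptor Sqstm1 (log2 change 0.32). The list's adjusted p was 0.00238, from 4.32e-04 by fry to an adjusted p = 0.201 with an estimated correlation, and a further quantile normalization ended it as well (0.114).

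Camera with the preset correlation called 2 lists of fat metabolism and fat cells higher at 11 months. The brightest 25% of all probesets also shifted upward, with a median log2 change of 0.09. The fatty acid oxidation list was bright on average (9.90 log2 units at 2 months, 10.04 at 11), as was the ubiquitin ligase and autophagy list (8.99 and 9.15). Whether either moved beyond other bright probesets was not tested. Of 21 fatty acid oxidation genes 6 rose and 0 fell (9 adjusted over the list alone), such as Acadm, a dehydrogenase of medium-chain fatty acids (log2 change 0.32, SE 0.06). Camera's adjusted p of 0.00399 ranged from 1.24e-04 to an adjusted p = 0.593 with an estimated correlation, and the call ended with quantile normalization (0.0953), the signal range as a covariate (0.328) and fry (0.0665). Adipocyte markers, which report fat cells in the dissected muscle, had 5 of 14 higher and 0 lower, with the desaturase Scd1 2.14-fold up (SE 0.28). Their adjusted p was 0.0227, from 9.20e-04 to an adjusted p = 0.593 with an estimated correlation. It was 0.106 by fry, and 0.0529 to 0.0937 without 2 months replicate 1, 11 months replicate 1 or 11 months replicate 3.

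In all, limma called 1820 probesets higher and 1099 lower at 11 than at 2 months, 19.1% of those tested, with a median size of 0.26 log2 units. Of these, 85 of the rises and 53 of the falls reached 1.5-fold. After a further quantile normalization the split was 1328 higher and 1214 lower. The number of calls fell from 2919 to 959 with the signal range as a covariate, to 1555 without the 3 arrays of narrowest range (2 months replicates 4 and 6, 25 months replicate 5), and to 1895 without 11 months replicate 5. Calls of 75 single genes, the unnamed pair included, were followed through the alternatives for this comparison. The covariate ended 22 of them, Dcn among these, and leaving out 1 array or another ended 9.

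The comparison of 25 with 11 months sets aged against adult muscle. Slc40a1, which encodes the iron exporter ferroportin, fell 1.65-fold, from 8.55 ± 0.19 to 7.83 ± 0.18 log2 units (SD, n = 6; adjusted p = 0.00921). Genes that respond to loss of nerve contact and form the acetylcholine receptor shifted upward together: 17 of 20 had a change above 0, with a mean log2 change of 0.15 (95% interval 0.10 to 0.20). Camera called this list (adjusted p = 4.76e-08, and adjusted p = 0.0112 with an estimated correlation). Kcnab1 rose by a further 0.59 ± 0.12 log2 units (SE; adjusted p = 0.0491), and the nerve-associated gene Nrep fell 1.56-fold (SE 0.11, adjusted p = 0.0337). A pair of probesets without a gene symbol, numbers 6912947 and 6921030, rose by 2.86 ± 0.13 and 2.21 ± 0.10 log2 units (SE; adjusted p = 2.48e-11 for each), after lower values at 11 than at 2 months; they were chosen after their values were seen.

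**Figure D2:**
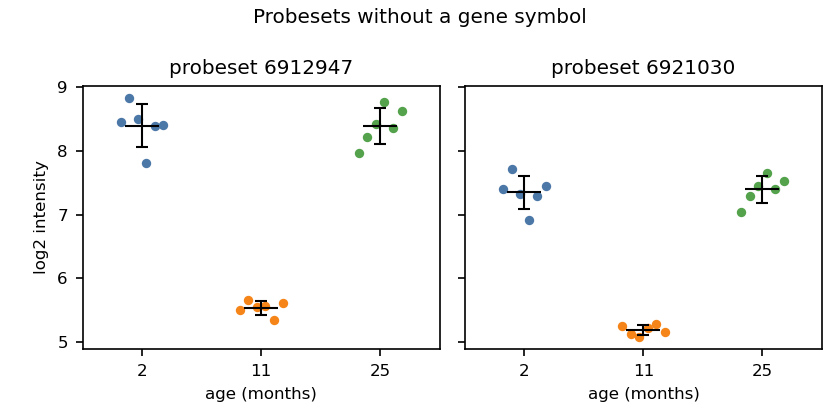
Log2 signal (vertical axis) of probesets 6912947 and 6921030 by age in months (horizontal axes); points are arrays, bars are the mean with the SD, n = 6. All 6 arrays of 11 months lie between 5.34 and 5.65 for the former and between 5.08 and 5.27 for the latter, below every other array.

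For the denervation and acetylcholine receptor list, 0 of 20 genes passed limma over all probesets and 8 rose adjusted over the list alone, while 10 had an unadjusted p under 0.05 and 6 passed the methods' one-way test with Tukey. Among the 8 were the stress gene Gadd45a (1.40-fold), the myogenic regulator Myog (1.27-fold), the receptor subunits Chrnb1 (1.26-fold) and Chrna1 (1.26-fold), the transcription factor Runx1 (1.22-fold) and the adhesion molecule Ncam1 (1.15-fold); over all probesets the 8 had adjusted p of 0.101 to 0.381. Myog had fallen by 0.58 log2 units from 2 to 11 months (adjusted p = 4.39e-04), and at 25 months it was 6.51 against 6.74 at 2 months. At the 3 ages Gadd45a was 8.24, 7.99 and 8.48, Runx1 6.69, 6.54 and 6.82, and Ncam1 6.94, 6.83 and 7.03. For 25 against 2 months limma did not call Runx1 (adjusted p = 0.331) or Ncam1 (adjusted p = 0.315), while it called Chrnb1 (adjusted p = 0.00103) and Chrna1 (adjusted p = 0.00222) higher. From 2 to 11 months the list had 2 genes higher and 2 lower and did not pass (adjusted p = 0.906). Chrna1, Runx1 and Ncam1 lay outside the rule for named genes and were chosen after their values were seen. Camera's adjusted p for the list was 4.76e-08, and over the alternatives it ranged from 8.93e-10 to an adjusted p = 0.0112 with an estimated correlation, the only 1 of the 87 list tests called with it. No alternative and no array left out ended the call.

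**Figure D3:**
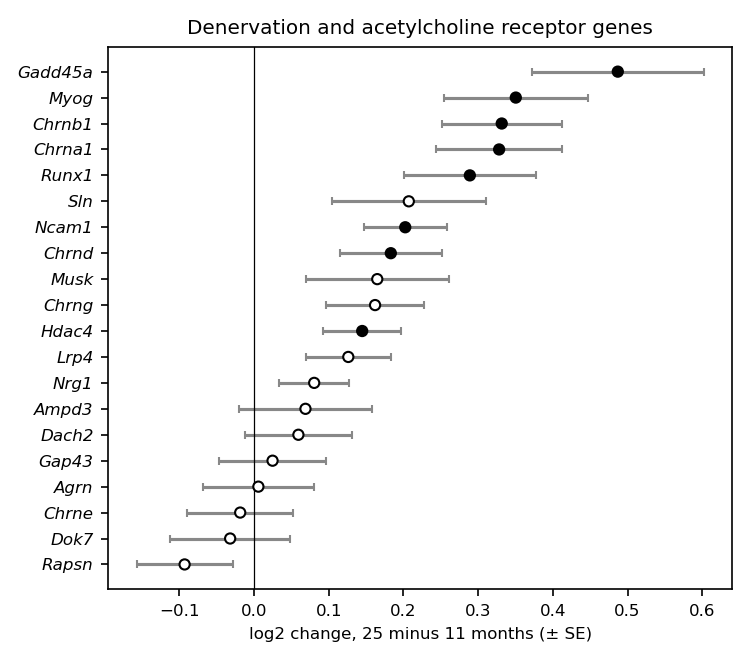
Log2 change from 11 to 25 months (horizontal axis) of the 20 measured denervation and acetylcholine receptor genes, with the SE; filled points passed when adjusted over the list alone. Gadd45a has the largest rise, 0.49, and 17 of 20 genes lie above 0.

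Camera with the preset correlation called 3 matrix and stromal lists lower at 25 than at 11 months, with 1 gene each past limma's test. The matrix protein Fn1 fell 1.33-fold (adjusted p = 0.04995), 1 of 30 collagen and matrix genes to do so; 18 fell adjusted over the list alone. Camera gave this list an adjusted p of 4.44e-16, from 3.59e-18 to an adjusted p = 0.123 with an estimated correlation. Fibro-adipogenic progenitor markers had 1 of 12 lower, Dpt (1.42-fold, SE 0.10), and 10 adjusted over the list alone. Their list's adjusted p of 3.11e-10 ranged from 3.23e-12 to an adjusted p = 0.0577 with an estimated correlation. Tenocyte markers had 1 of 8 lower, the cartilage and tendon protein Chad (1.75-fold, SE 0.15), and 4 adjusted over the list alone. For these it was 7.14e-05 and ranged from 7.97e-07 to an adjusted p = 0.131 with an estimated correlation.

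All 14 adipocyte markers had values below 0 for 25 against 11 months, with a mean log2 change of -0.34 (95% interval -0.60 to -0.08); 0 passed limma over all probesets, 9 had an unadjusted p under 0.05, 2 passed the one-way test with Tukey and 2 fell adjusted over the list alone. Camera's adjusted p of 4.76e-08 ranged from 2.54e-13 to an adjusted p = 0.148 with an estimated correlation. Endothelial markers had 0 of 14 past limma's test, 5 at an unadjusted p under 0.05, 1 by the one-way test and 2 lower adjusted over the list alone (adjusted p = 0.00367, from 5.68e-04 to an adjusted p = 0.188 with an estimated correlation). Slow fibre genes had all 11 members above 0 and a mean of 0.25 (95% interval -0.09 to 0.60), with 0 past limma's test, 0 at an unadjusted p under 0.05 and 0 by the one-way test. The list's adjusted p of 4.70e-04 ranged from 1.78e-06 to an adjusted p = 0.451 with an estimated correlation, and fry gave 0.237.

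Camera with the preset correlation also called 3 energy metabolism lists lower at 25 than at 11 months, but 0 members passed limma's test and the 95% intervals of the mean log2 change included 0: -0.17 to 0.003 for oxidative phosphorylation, -0.12 to 0.002 for glycolysis and -0.22 to 0.05 for fatty acid oxidation. Unadjusted p was under 0.05 for 3 of 29 oxidative phosphorylation, 4 of 14 glycolysis and 3 of 21 fatty acid oxidation genes, and the one-way test with Tukey called 0, 5 and 0. These lists were bright on average, and the brightest 25% of all probesets also shifted downward, with a median log2 change of -0.03. Whether the lists moved beyond other bright probesets was not tested. For oxidative phosphorylation 28 of 29 genes had values below 0, and camera's adjusted p was 7.14e-05, from 8.20e-09 to an adjusted p = 0.433 with an estimated correlation. Fry gave 0.137. Glycolysis and glycogen genes had an adjusted p of 0.00563, from 0.00354 to an adjusted p = 0.427 with an estimated correlation. Fry gave 0.0665. For fatty acid oxidation the adjusted p of 0.0248 ranged from 1.05e-04 to 0.681, with the signal range as a covariate, and became an adjusted p = 0.636 with an estimated correlation. Quantile normalization (0.101), the fit without the 3 narrowest arrays (0.144) and fry (0.397) ended the call too. It was 0.0727 to 0.207 without 11 months replicate 1, 3 or 5 or 25 months replicate 2, 4 or 5.

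Of the immune lists, camera with the preset correlation called antigen presentation and T and NK cells higher, again with 0 members past limma's test or the one-way test and with 95% intervals that included 0 (-0.04 to 0.28 and -0.04 to 0.19); 1 antigen presentation gene and 0 T and NK cell markers had an unadjusted p under 0.05. Antigen presentation and interferon genes had 15 of 16 values above 0. Their list's adjusted p of 0.00563 ranged from 5.13e-04 to an adjusted p = 0.433 with an estimated correlation, with 0.222 by fry and 0.0786 without 25 months replicate 1 and 0.0687 without 25 months replicate 2. T and NK cell markers had 11 of 12 values above 0 and a mean log2 change of 0.07. These markers were dim, with a mean of 5.05 log2 units at 11 months and 5.12 at 25 months. The dimmest 25% of all probesets also shifted upward, with a median log2 change of 0.04. Whether the T and NK cell list moved beyond other dim probesets was not tested. For that list the adjusted p of 0.0251 ranged from 0.00716 to an adjusted p = 0.540 with an estimated correlation, with 0.228 after quantile normalization, 0.328 with the signal range as a covariate and 0.286 by fry. It was 0.0551 to 0.111 without 11 months replicate 3 or 5 or 25 months replicate 5. The macrophage list (mean log2 change -0.03, adjusted p = 0.576), B and plasma cells (adjusted p = 0.162) and neutrophils (adjusted p = 0.148) did not pass.

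The remaining named calls for 25 against 11 months were Cpne2 (1.54-fold higher), the glycogen-binding protein Stbd1 (1.45-fold higher, after a fall from 2 to 11 months), Cyfip2 (1.44-fold higher) and AI593442 (log2 change 0.27), and lower values of the neurotrophin receptor Ntrk2 (1.30-fold), Dhrs7c (1.28-fold), Igfbp6 (1.26-fold), Serpinf1 (1.26-fold) and the p53 target Phlda3 (1.24-fold), with adjusted p of 0.0337 to 0.04995. Every array lay apart for 3 of the 5 rises and 7 of the 10 falls of the rule (0.216% of splits for unpicked genes, so again no test of genes picked by their change). The exceptions were Kcnab1, AI593442, Chad, Dpt and Ntrk2. Levels of Col1a1 (log2 change -0.77, adjusted p = 0.126), Col3a1 (-0.67, adjusted p = 0.125), Actc1 (0.61, adjusted p = 0.335), Ostn (0.49, adjusted p = 0.462) and Amy1 (0.53, adjusted p = 0.165) did not pass.

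Limma called 23 probesets between 11 and 25 months, 9 higher and 14 lower, or 0.150% of those tested. The split was 11 to 9 after quantile normalization and 9 to 7 after median centring, and 1591 had an unadjusted p under 0.05. The count was 3 without any of 11 months replicates 4 and 5 and 25 months replicates 2, 3 and 4, 4 without 11 months replicate 2, 6 without 25 months replicate 6, 7 without 11 months replicate 6, 9 without 11 months replicate 1, and 12 without 2 months replicate 3 or 11 months replicate 3. Of the 15 genes named by the rule, the call of 14, all but Slc40a1, ended on leaving out any of 7 to 15 arrays, with adjusted p up to 0.146. The methods' one-way test with Tukey called 461 probesets, array weights 185, and the signal range as a covariate 37, of which 27 were higher and 10 lower. Tukey's p was not adjusted across probesets, so the 461 and the 23 do not share a threshold.

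The comparison of 25 with 2 months sets aged against young muscle. Col1a1 fell 8.09-fold, from 11.49 ± 0.52 to 8.47 ± 0.28 log2 units (SD, n = 6; adjusted p = 9.34e-09), Actc1 6.29-fold, and Col1a2 5.20-fold, and Col3a1 fell to 8.20 ± 0.23 from 10.20 ± 0.48. Ostn rose 6.32-fold to 10.43 ± 0.21 (adjusted p = 1.26e-07), Amy1 4.10-fold, Kcnab1 3.94-fold and Eda2r, a receptor gene induced by p53, 2.97-fold. Further rises were in Ppp1r14bl (2.68-fold), Cyfip2 (2.47-fold), Hook1 (2.42-fold), Klhl38 (2.31-fold), Gpx3 (2.31-fold) and Aldh1a1 (2.27-fold), and further falls in Kera (2.88-fold), Nrep (2.69-fold), Sparc (2.61-fold), Chad (2.46-fold), the spermine oxidase Smox (2.23-fold) and H19 (2.18-fold). For all 10 rises and all 10 falls of the rule every array lay apart, which tests nothing for genes picked by their change (0.216% of splits for unpicked genes).

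Of 30 collagen and matrix genes 25 fell and 0 rose by 25 months (26 and 1 adjusted over the list alone), with a mean log2 change of -0.76 (95% interval -0.90 to -0.61). The adjusted p of 4.65e-27 ranged from 2.77e-32 to an adjusted p = 0.0577 with an estimated correlation. Tenocyte markers fell alongside, 7 of 8 (adjusted p = 8.03e-10, from 1.26e-11 to an adjusted p = 0.0573 with an estimated correlation). So did 7 of 12 fibro-adipogenic progenitor markers, 9 adjusted over the list alone, led by Mfap4 (1.96-fold, SE 0.09) and Mfap5 (1.44-fold). Their adjusted p of 3.22e-06 ranged from 4.35e-08 to an adjusted p = 0.123 with an estimated correlation. Endothelial markers had 6 of 14 lower and 8 adjusted over the list alone (adjusted p = 0.00414, from 1.54e-04 to an adjusted p = 0.192 with an estimated correlation). Adipocyte markers had 2 of 14 lower and a mean change of -0.02, and the list did not pass (adjusted p = 0.533).

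Denervation and acetylcholine receptor genes had 7 of 20 higher and 0 lower at 25 than at 2 months (8 and 1 adjusted over the list alone): Musk, the kinase that organises the neuromuscular junction, rose 1.55-fold (SE 0.10), Chrnb1 1.34-fold and Chrna1 1.32-fold. Camera's adjusted p was 0.00574, and over the alternatives it ranged from 2.05e-04 by fry to an adjusted p = 0.123 with an estimated correlation. Slow fibre genes had 6 of 11 higher and 0 lower (8 adjusted over the list alone), with the slow troponin Tnni1 1.87-fold up (SE 0.21) and Fhl1 1.41-fold. The adjusted p of 3.07e-04 ranged from 9.94e-06 to an adjusted p = 0.433 with an estimated correlation. Fast fibre genes had 1 higher and 2 lower of 13, and the list did not pass (adjusted p = 0.135).

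Further lists passed at 25 against 2 months. The brightest 25% of all probesets shifted upward there, with a median log2 change of 0.07. How the lists called higher compare with other bright probesets was not tested. Imprinted and growth genes had 6 of 14 lower and 1 higher, with Igf1 1.69-fold down (SE 0.10) and Peg3 1.58-fold. The adjusted p of 0.00766 ranged from 2.92e-05 by fry to an adjusted p = 0.123 with an estimated correlation. Ubiquitin ligase and autophagy genes had 7 of 19 higher and 0 lower, with Fbxo32 1.90-fold up. The adjusted p of 0.00766 ranged from 0.00186 by fry to an adjusted p = 0.284 with an estimated correlation, and it was 0.115 after quantile normalization. Circadian clock genes had 5 of 15 higher and 1 lower, with the repressor Cry2 1.83-fold up (SE 0.08) and Rora 1.27-fold. Camera's p for the clock list was an adjusted 0.0207. Over the alternatives it ranged from 5.01e-05 by fry to an adjusted p = 0.123 with an estimated correlation, and it was 0.114 after quantile normalization.

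**Figure D4:**
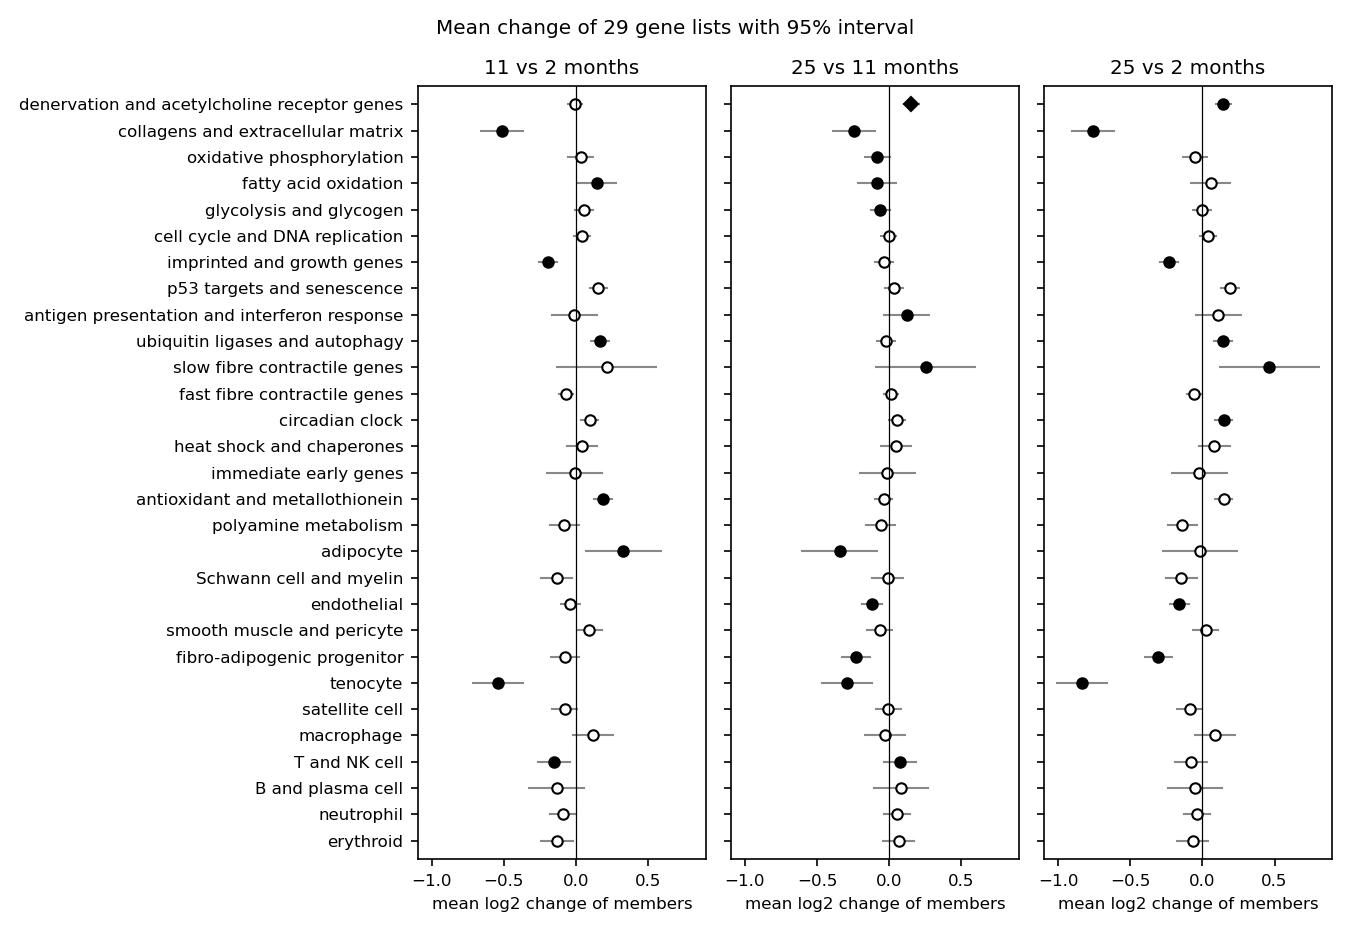
Mean log2 change with its 95% interval (horizontal axes) of the 29 gene lists in the 3 comparisons; filled points passed camera with the preset correlation and the diamond also with an estimated correlation. Collagen and matrix genes lie at -0.51, -0.24 and -0.76, and the diamond is the denervation list at 0.15 for 25 against 11 months.

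Limma called 1602 probesets higher and 1064 lower at 25 than at 2 months, 17.4% of those tested. The split was 1492 to 1310 after quantile normalization, 1387 to 1149 with the signal range as a covariate and 1721 to 990 after median centring. Of these, 109 of the rises and 90 of the falls reached 1.5-fold. Of the 2919 probesets that differed between 11 and 2 months, 1776 differed in the same direction between 25 and 2 months and 1 in the opposite direction. Both comparisons use the same 2-month arrays; independent lists would share 267. Across probesets, which are not independent replicates, the 2 sets of changes correlated with r = 0.83, against 0.50 in simulations of unchanged groups that share these arrays. With the 2-month arrays split into sets of 3, a separate set for each comparison, the changes correlated with r of 0.47 to 0.72 over 20 splits. In these splits 280 to 603 probesets were shared, where independent lists of the same sizes would share 33.6 to 181. Of the 23 probesets that differed between 11 and 25 months, 17 also differed between 2 and 11 months, 10 of them in the same direction, among which were Nrep, Kcnab1 and Cyfip2, and 7 in the opposite direction, such as Phlda3 and Stbd1. These comparisons share the 11-month arrays, which pushes their changes in opposite directions. The correlation was -0.50 simulated and -0.29 observed, but the covariance was -0.0034 simulated and -0.0060 observed. The weaker correlation therefore does not show weaker opposition. Independent lists would share 4.39 probesets, a figure that does not allow for the shared arrays.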

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

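The tests of the unnamed probeset pair and of the share of higher calls were chosen after those results were seen; the tests of the skin genes and of other splits of the arrays were written before. Of 381 groups of 6 arrays examined, 22 held an array set apart from the other 5 by a gap larger than Dixon's 95% limit, where chance gives 19.1.

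The pair of probesets without a gene symbol, 6912947 and 6921030, was low in all 6 arrays of 11 months. Values there were 5.34 to 5.65 and 5.08 to 5.27 log2 units, against 7.81 to 8.83 and 6.92 to 7.71 at 2 months and 7.98 to 8.76 and 7.04 to 7.65 at 25 months. With the signal range as a covariate the smaller rise from 11 to 25 months was still 2.21, which argues against the signal range. A genetic difference between the 11-month mice and the others stays open: 2 probesets, this pair, set the 11-month arrays apart by at least 1 log2 unit (3 did so for 2 months and 0 for 25 months), but that count restates the pattern and decides nothing. An effect of age stays open as well, untested.

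Hair and skin genes were raised in the 11 months replicate 4 array. The 16 genes that first showed it averaged 8.29 there, against 5.37 to 6.05 in the other arrays of that age; the hair follicle keratin Krt71 reached 10.07 against 5.50 elsewhere. Of 18 further epidermal markers listed before the test, 13 were highest there, where 1 would be by chance; their mean was 6.28 against 5.63 to 5.78, an excess of 0.58 ± 0.07 (SE); 2 of them lay above the median signal in the other arrays (Jup, the brightest, was 9.62 there against 9.20), and 0 are in the fixed lists. After quantile normalization the excess was 0.56, which argues against the signal range, so skin or hair carried into this sample is a candidate source; no biological explanation was tested. Melanocyte markers were set apart in the same array (5.64 against 5.33 to 5.40), with 3 of 6 highest there and an excess that 383 of 10000 random lists matched.

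More probesets were higher than lower at 11 than at 2 months, 62.4% of the calls. After a further quantile normalization the share was 52.2%, but that step gives all arrays 1 distribution and so evens the balance whatever its cause. It was 56.3% after median centring and 54.5% (523 higher, 436 lower) with the signal range as a covariate, but the mean range was 0.14 wider at 11 months, so the covariate may also take up part of an age effect, and a difference in array signal range stays open as a cause. Without the 3 arrays of narrowest range it was 65.0%, so those arrays are not its only source. That fit made fewer calls (1555), and with all arrays the share also rose when fewer were called (71.1% of 1256 at an adjusted p under 0.01). Whether those arrays add a part of the imbalance therefore stays open. Whether the range itself differs with age through technical handling or biology stays open, since the labels give no batches.

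Chance alone is an unlikely source of each count: of 100 splits of the arrays, the real 1 included, 1 called as many probesets. That is the smallest share that 100 splits can give. Splits cannot separate age from a batch that goes with it, and the labels give no batches. For 11 against 2 months the real count was 2919 and the highest other 1701, for 25 against 11 months 23 and 2, for 25 against 2 months 2666 and 2302, and for the 3 ages together 2936 and 1758.

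The remaining arrays set apart from the other 5 of their age are given as values. Gpx3 was 9.16 in 11 months replicate 2 (others 8.73 to 8.89). Kera was 6.25 in 2 months replicate 4 (others 7.04 to 7.52) and 5.21 in 25 months replicate 4 (others 5.54 to 5.64). Mettl21e was 5.40 in 11 months replicate 3 (others 4.97 to 5.13) and Igfbp6 was 8.23 in 11 months replicate 5 (others 7.92 to 8.03). Cox5a was 9.49 in 25 months replicate 5 (others 9.73 to 9.83) and Pgam2 was 12.12 in 11 months replicate 2 (others at most 12.04). B2m was 10.39 in 11 months replicate 5 (others 9.94 to 10.07). Hspb8 was 11.25 in 11 months replicate 1 (others 11.59 to 11.79) and 11.49 in 25 months replicate 6 (others 11.71 to 11.79). Chodl was 6.39 in 2 months replicate 4 (others 6.81 to 7.05).

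Means over gene lists stood apart in the following arrays. The oxidative phosphorylation list was 10.90 in 2 months replicate 4 (others 10.99 to 11.02). In 2 months replicate 6, antigen presentation was 6.98 (others 6.60 to 6.65) and the B and plasma cell list 5.85 (others 5.20 to 5.33). Heat shock was 9.54 in 11 months replicate 5 (others 9.33 to 9.39) and the Schwann cell list 6.55 in 11 months replicate 1 (others 6.16 to 6.30). Smooth muscle was 8.20 in 2 months replicate 1 (others 8.07 to 8.10). In 25 months replicate 5, T and NK cell markers were 5.24 (others 5.07 to 5.13) and melanocyte markers 5.51 (others 5.38 to 5.43).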

How the results depend on the processing

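The signal range covariate, the fits without the 3 narrowest arrays and the list tests without 11 months replicate 4 were chosen after seeing the data. No named gene or list call reversed. The balance for 25 against 11 months (9 higher, 14 lower) turned to 27 and 10 with the covariate, 11 and 9 after quantile normalization and 9 and 7 after median centring. Calls of named genes and of the unnamed pair passed in 1273 of 1360 alternatives and in 2831 of 3060 with 1 array left out. List calls passed in 153 of 203 and 506 of 522, and the estimated correlation ended 28 of the 29 list calls. These tallies leave out the dim-probeset filter, 1 probeset per gene, the stricter thresholds and the fits of 2 ages, where only counts were made. The list tallies also leave out array weights, the trended and robust variance model and the one-way test. For 25 against 11 months (23 calls) the count was 185 with array weights, 37 with the signal range as a covariate, 461 by the methods' one-way test with Tukey, 8 with 1 probeset per gene, 45 with only the 2 ages fitted, 3 at an adjusted p under 0.01 and 8 at 1.5-fold. With a replicate block it was 6; paired replicate numbers had correlations of -0.33 to 0.42 and 8 of 36 matched best, so samples were not treated as paired. For 11 against 2 months (2919) it was 959 with the covariate, 1555 without the 3 narrowest arrays, 1256 at 0.01 and 138 at 1.5-fold. For the 3 ages (2936) it was 1754 without the narrowest arrays, 1484 at 0.01 and 226 at 1.5-fold; for 25 against 2 months (2666), 1419 and 199. Stricter thresholds, fewer probesets and fewer arrays change counts by construction. For 25 against 11 months that does not account for the 8 calls with 1 probeset per gene (2 higher, 6 lower). The 23 calls covered 18 distinct named genes, and the rule had named 5 rises and 10 falls. Some of these named calls therefore ended in that fit. The one-way test counts at another threshold, as its Tukey step is not adjusted across probesets. For array weights, the covariate, the block and the fit of 2 ages the cause was not tested. Of the 2919 calls, 839 were kept with the covariate and 1995 after quantile normalization. Leaving out 1 array gave 1895 to 3787 (11 against 2 months; lowest without 11 months replicate 5), 3 to 33 (25 against 11), 2081 to 3025 (25 against 2) and 2326 to 3452 (3 ages). No background probes could be identified, so the limit that background sets for dim probesets is unknown.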

Other observations

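The range covariate named here was chosen after the data were seen. Of 17 antioxidant and metallothionein genes 6 rose and 1 fell at 11 months, and 5 rose and 0 fell at 25 months: Gsta4, a glutathione transferase, rose 1.55-fold at 11 months (SE 0.07) and 1.54-fold at 25. Camera's adjusted p at 11 months was 0.0227, and over the alternatives it ranged from 2.29e-04 by fry to an adjusted p = 0.208 with an estimated correlation. It was 0.144 after quantile normalization and 0.0612 with the range covariate. This list was bright on average (8.61 log2 units at 2 months, 8.79 at 11), and the brightest 25% of all probesets shifted upward too, by a median of 0.09. At 25 against 2 months camera's adjusted p was 0.195 and fry's 0.00435, with a mean change of 0.15 and a median of -0.06. Heat shock genes had 2 of 19 higher at 11 months and 5 at 25 months, with the small chaperone Hspb7 1.56-fold up at 25 months (SE 0.11), and the list did not pass (adjusted p = 0.578 and 0.140). Genes of p53 and senescence had 3 of 16 higher at 11 months and 4 at 25, with the cell-cycle inhibitor Cdkn1a 1.56-fold up at 25 months (SE 0.13). The list did not pass camera (adjusted p = 0.158 and 0.101), while fry gave adjusted p of 0.00489 and 0.00227. Its mean log2 change had 95% intervals of 0.09 to 0.22 at 11 months and 0.13 to 0.25 at 25.

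Polyamine genes went both ways: 1 of 9 rose and 3 fell at 25 against 2 months, with the spermine synthase Sms 1.42-fold up beside the fall of Smox. Glycolysis and glycogen genes did so too, 3 of 14 higher and 2 lower at 11 months, with the glycogen synthase Gys1 1.31-fold up (SE 0.04) while Pgam2 fell by 0.32 log2 units. Oxidative phosphorylation genes had 5 of 29 lower at 25 against 2 months, such as Cox5a (1.27-fold) and Cyc1 (1.16-fold), and 2 higher at 11 months. Cell cycle genes had 4 of 22 higher and 1 lower at 11 months, with the cyclin Ccne2 1.32-fold up, while the list's median was -0.01 and its mean 0.04. Immediate early genes had 2 of 18 higher at 11 months, among them Ccn1 (1.47-fold, SE 0.14). Fast fibre genes had 3 of 13 lower at 11 months, such as Mylpf (1.18-fold).

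At 11 against 2 months the T and NK cell list had 2 of 12 lower (camera's adjusted p = 0.00542). The adjusted p ranged from 0.00239 to an adjusted p = 0.433 with an estimated correlation. It was 0.0846 after quantile normalization and 0.132 with the range covariate. The list's mean log2 change was -0.15, at a dim mean signal of 5.20 log2 units at 2 months and 5.05 at 11 months. The dimmest 25% of all probesets shifted the same way, with a median log2 change of -0.08. The T and NK cell list was highest in 2 months replicate 6 (5.41, others of that age 5.08 to 5.28). That array also stood apart for antigen presentation and for B and plasma cells. Leaving out any 1 array did not end the T and NK cell call. Satellite cell markers had 1 of 11 higher, Des, also the main intermediate filament of muscle fibres (log2 change 0.32), and 3 lower, among them Chodl (1.27-fold); from 11 to 25 months that list's mean was -0.01 while its test pointed up (adjusted p = 0.892). Smooth muscle and pericyte markers had 2 of 12 higher, led by Rgs5 (log2 change 0.32). Macrophage markers had 2 of 14 higher, Schwann cell markers 1 of 10 lower, and neutrophil markers 1 of 9 lower. B and plasma cell markers (8) and erythroid markers (3) had 0 members called at 11 months by limma or the one-way test, 1 and 2 at an unadjusted p under 0.05, and adjusted p of 0.194 and 0.184. Adjusted over the list alone 2 of the 3 erythroid markers were lower, and fry gave that list 0.00957. Antigen presentation genes had 1 of 16 higher and 2 lower at 11 months, and 1 higher at 25 months, B2m (1.58-fold, SE 0.11).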
